A study of Mus musculus with 16 samples.

How the data were processed

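Labelled RNA from gastrocnemius muscle of untreated female C57Bl/6J mice was measured on Agilent 1-colour (Cy3) arrays, 1 array per sample, with 4 samples at each of 3, 15, 24 and 29 months. Per the file headers, the scanner files hold spot brightness as intensity, from Feature Extraction 10.7.1.1, which found the spots, marked outliers and subtracted background with spatial detrending, with no normalization between arrays. The deposited series table holds log2 values with nearly equal distributions on the 16 arrays. Its probe names did not match the scanner files (r -0.005 to 0.0183 across probes), whereas its order by feature number did (r 0.985 to 0.993 across probes, which are not independent replicates). It was therefore joined by feature number and used only as an alternative. How the authors made these values is not given in the sources used here.

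Each array had 62976 spots, 59305 of them not controls. Spots marked as outliers were left out, and 93 probes were dropped for this, leaving 55588 probes. Of these, 26540 matched 1 gene each in the RefSeq table of assembly GRCm38.p6 (20122 genes), used for names only, and 29048 kept the names in the files. As the headers name another build, no coordinates are given. Signals were log2 transformed and the 75th percentile of each array was subtracted. A probe was kept if it was well above background on all 4 arrays of at least 1 age, which left 28435 probes. A gene was represented by its kept probe of highest mean, giving 21777 genes, 13355 with a RefSeq symbol and 4710 with more than 1 kept probe.

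Groups were taken from the sample labels. Linear models were fitted with limma 3.58.1 in R 4.3.3 to the means of the 4 ages over all 16 arrays (12 residual degrees of freedom, moderated by eBayes with 2.73 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over genes. A gene was called changed at adjusted p under 0.05. The 5 comparisons of ages, a straight line in age with slide as a block, the difference between the steps from 3 to 15 and from 24 to 29 months, and the overlap of 24 and 29 against 3 months were chosen before the data were examined, as were the gene lists, the rule for named genes and the alternatives, except those said to be chosen later. The slide and array position come from the file headers. Slide could not be a term in the model of group means because each age lay on 1 slide. Replicate numbers follow the array column and were not used as a block.

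Gene lists (29) were tested in each comparison by limma's camera with a preset correlation of 0.01, with adjustment over all 145 tests, and beside it by camera with an estimated correlation and by fry. The lists were denervation response, embryonic and neonatal muscle, slow fibre, fast fibre, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, atrophy programme, autophagy and lysosome, p53 and cell cycle arrest, antioxidant and stress, collagen and extracellular matrix, complement, interferon response, cell proliferation, growth factor and insulin signalling, circadian clock, immediate early genes, and markers of macrophages, T and NK cells, B and plasma cells, adipocytes, satellite cells, fibroblasts, endothelium, smooth muscle and pericytes, nerve and Schwann cells, tendon and erythroid cells. Marker lists describe transcript levels in whole muscle, not cell numbers.

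Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes whose 4 arrays of an age all lay above the 4 of the other (2.86% of genes by chance), leaving out names that are clone, locus or probe identifiers. To these were added the 2 members of each list with the smallest p, 26 fixed genes, of which 25 were measured, and the 5 highest and 5 lowest coefficients of the line and of the difference of steps. Further members named where a count was 5 or fewer, such as Hdac9, Chad and Mustn1, were chosen after their values were seen. Some genes that the rule names are not reported here. A fold is given as a bound, at least so many times, where no array of the lower age was well above background. The bound takes each array of that age at its signal or at the lowest signal marked well above background on that array, whichever was higher. Signals above that lowest value were not always marked, so the bound is approximate.

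The alternatives were quantile normalization, scaling by the median, normexp background correction, the deposited log2 values, no filter and a filter on all arrays, the mean over probes, a fit of only the ages compared, a block on replicate number, eBayes with trend and robust, array weights, at least 1.5-fold, slide as a random block, and leaving out each array. The planned normexp on mean spot signals was not run, because the scanner files used here gave median and not mean spot signals, and median signals took their place with an offset of 50. That setting and the fits without the 2 and the 4 arrays of lowest weight were chosen after seeing the data. On simulated data with 200 changed genes among 21777, the fit for 29 against 3 months recovered 41.8% of 1.5-fold, 79.1% of 2-fold and 95.5% of 4-fold changes and called 9 unchanged genes. For 29 against 24 months it recovered 31.3%, 71.6% and 90.9%, and for the line 0%, 19.4% and 60.6%. The simulated genes were independent and had the same spread at every age. The measured arrays of the old ages varied more, so these shares may not hold for them. Overlap was simulated with 100 draws of unchanged groups against the same 3 month arrays.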

Results

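Gene expression was measured in gastrocnemius muscle, a calf muscle of mainly fast fibres, from untreated female C57Bl/6J mice, an inbred laboratory strain, at 3, 15, 24 and 29 months of age. Each age had 4 samples, each on 1 array of a 1-colour platform that reads the brightness of labelled RNA on probes. The comparisons asked how transcript levels in the muscle differed between adult and old ages. Of the spots that were not controls, 48.0% to 60.9% were well above background on an array, none was saturated, and 21777 genes were tested. The arrays of 3 and 15 months lay on slide 1 and those of 24 and 29 months on slide 2. The comparisons of 15 with 3 months and of 29 with 24 months therefore lay within 1 slide, and the other 3 spanned both. Nothing in the labels says that the 4 samples of an age came from separate animals, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

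Samples of the old ages differed more among themselves than the younger ones. In the weights that limma estimates from the spread of each array, 29 months replicate 1 (0.26), 24 months replicate 2 (0.37), 29 months replicate 3 (0.42) and 24 months replicate 4 (0.51) were lowest, and the other arrays lay between 0.99 and 2.07. These arrays stood apart in markers of cells other than muscle fibres, scored as the mean log2 deviation of a list from its mean over the 16 arrays. At 29 months, replicate 1 scored 2.84 for T and NK cell markers against -0.25 to -0.05 on the other arrays of that age. The same array scored 1.79 for B and plasma cell markers, 1.48 for interferon response genes and 0.99 for macrophage markers. At 24 months, replicate 4 scored 2.42 for adipocyte markers against 0.15 to 0.21 on the others. Scores of collagen and matrix genes were lowest on 24 months replicate 2 (-1.34) and 29 months replicate 3 (-1.37), which also had the lowest fibroblast marker scores (-1.56 and -0.95).

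**Figure D1:**
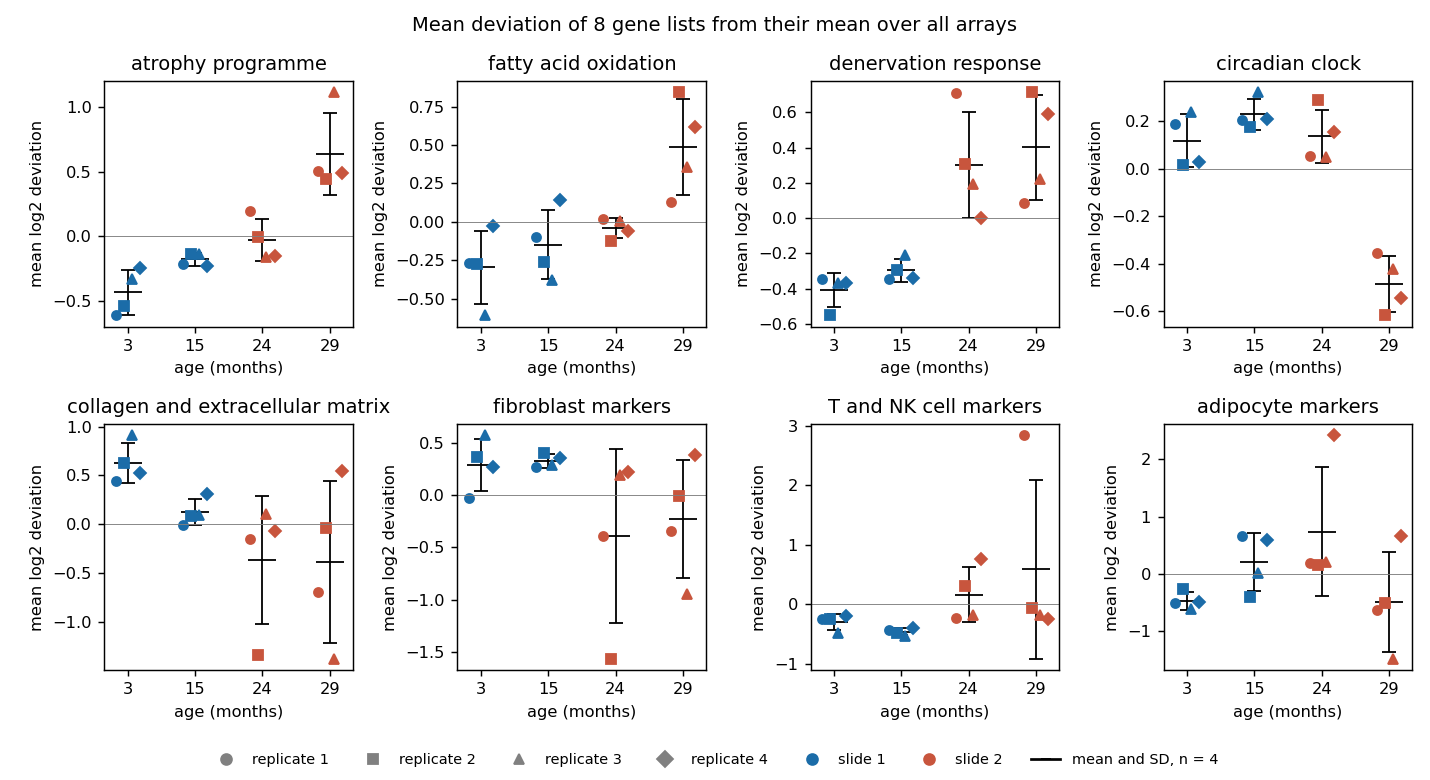
Scores of 8 gene lists (vertical axis, mean log2 deviation from the mean over the 16 arrays) at each age in months (horizontal axis), 1 point per array shaped by replicate and coloured by slide, with the mean and SD of the 4 arrays. The circadian clock scores of the 4 arrays of 29 months (-0.62 to -0.36) lay below those of the 12 younger arrays, and 29 months replicate 1 stood apart at 2.84 for T and NK cell markers.

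At 29 months, compared with 3 months, the muscle had higher levels of several genes of protein breakdown, fatty acid use and denervation, and lower levels of several collagens and of the clock genes Dbp and Hlf. The limma fit called 3190 of 21777 genes changed after Benjamini-Hochberg adjustment, 1522 higher and 1668 lower at 29 months, and 1951 of them changed at least 1.5-fold. Of these 3190, 486 were also called in the same direction in a comparison within 1 slide, 160 of them at 15 against 3 months and 338 at 29 against 24 months. Independent lists would share 15.3 and 29.8. As each of the 2 comparisons shares the arrays of 1 age with 29 against 3 months, some agreement arises from these arrays alone. Fitted on the 8 arrays of these ages alone, limma called 1983 genes, and with arrays scaled to their median instead of their 75th percentile 1537.

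**Figure D2:**
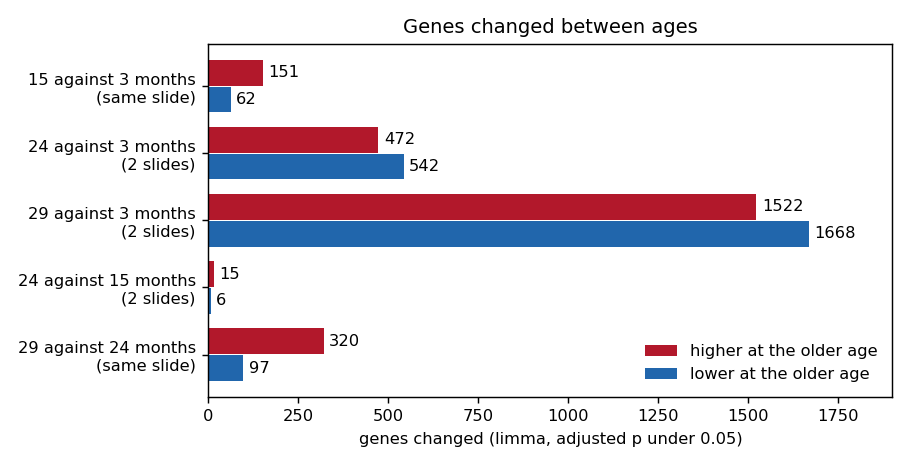
Number of genes (horizontal axis) called higher or lower by limma at the older age in each of the 5 comparisons of ages (vertical axis), which are marked as lying on the same slide or on 2 slides. The comparison of 29 with 3 months had 1522 higher and 1668 lower genes, and that of 24 with 15 months 15 and 6.

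Several genes of the atrophy programme rose at 29 against 3 months. Fbxo32 (atrogin-1) and Trim63 (MuRF1), ubiquitin ligases of muscle atrophy, were 6.56-fold (log2 change 2.72, SE 0.38, adjusted p = 0.000327) and 4.99-fold higher (log2 change 2.32, SE 0.31, adjusted p = 0.000265). The mean log2 signal of Fbxo32 was 11.66 ± 0.84 at 3 months and 14.37 ± 0.71 at 29 months (SD, n = 4). Metallothionein Mt2 was 13.0-fold higher (log2 change 3.70, SE 0.38, adjusted p = 3.12e-05). Of 19 measured members, 12 were higher and 0 lower, and adjusted over the list alone 12 were higher and 2 lower. The list was called higher (median log2 change 0.78, adjusted p = 3.02e-08). The atrophy programme list had adjusted p = 0.369 with an estimated correlation. Among autophagy genes Gabarapl1, a protein of autophagosome membranes, was 3.82-fold higher (log2 change 1.94, SE 0.19, adjusted p = 2.52e-05) and Ulk1, a kinase that starts autophagy, 1.65-fold higher (log2 change 0.72, SE 0.15, adjusted p = 0.0047). In that list 10 of 24 were higher and 1 lower, 11 and 2 adjusted over the list alone (median log2 change 0.31, adjusted p = 0.00144). The autophagy and lysosome list had adjusted p = 0.72 with an estimated correlation. Within slides, the atrophy list had a median change of 0.10 at 15 against 3 months and 0.46 at 29 against 24 months, and the autophagy list 0.04 and 0.17.

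Several fatty acid oxidation genes were higher at 29 than at 3 months. Pdk4, the kinase that switches off pyruvate dehydrogenase, was 10.8-fold higher (log2 change 3.44, SE 0.27, adjusted p = 6.97e-06), with mean log2 signals of 13.87 ± 0.25 and 17.30 ± 0.17 (SD, n = 4). Ucp3, a mitochondrial uncoupling protein of muscle, was 4.46-fold higher (log2 change 2.16, SE 0.24, adjusted p = 7.05e-05), Angptl4, an inhibitor of lipoprotein lipase, 13.6-fold higher (log2 change 3.76, SE 0.45, adjusted p = 0.000123), and Acot1, an acyl-CoA thioesterase, 20.8-fold higher (log2 change 4.38, SE 0.32, adjusted p = 3.73e-06). Of 24 members of the fatty acid oxidation list, 10 rose and 0 fell, 13 and 0 adjusted over the list alone (median log2 change 0.53, adjusted p = 5.02e-08). The fatty acid oxidation list had adjusted p = 0.708 with an estimated correlation. Within slides its median change was 0.00 at 15 against 3 months and 0.31 at 29 against 24 months. Ppargc1a, a coactivator of mitochondrial genes, rose 1.97-fold (log2 change 0.98, SE 0.23, adjusted p = 0.0109). Of the 49 oxidative phosphorylation genes limma called 0, over all genes or over the list alone, and 3 had an unadjusted p under 0.05. Their median change was -0.16 (adjusted p = 0.00837, and adjusted p = 0.805 with an estimated correlation), and without 29 months replicate 1 or 3 months replicate 4 the list was no longer called, with adjusted p up to 0.426. Without the 4 arrays of lowest weight the median was 0.043. Glycolysis and glycogen genes had 2 of 17 lower, Pgam2 and Phkg1, over all genes and over the list alone, and the list was not called (median log2 change -0.13, adjusted p = 0.158). The glycolysis and glycogen list had adjusted p = 0.818 with an estimated correlation. The call of Pgam2 was lost without any 1 of 3 months replicates 3 and 4 or 29 months replicates 1 and 3, and that of Phkg1 without any 1 of 3 months replicates 2 and 3 or 29 months replicates 1 and 2, with adjusted p up to 0.0691 and 0.0709.

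Several denervation genes rose at 29 against 3 months. Runx1, a transcription factor induced by denervation and above background on 3 of the 4 arrays of 3 months, was 7.42-fold higher (log2 change 2.89, SE 0.35, adjusted p = 0.000149) and Gadd45a 4.82-fold higher (log2 change 2.27, SE 0.24, adjusted p = 3.76e-05). Musk, the receptor kinase of the neuromuscular junction, rose 3.06-fold (log2 change 1.61, SE 0.24, adjusted p = 0.0006) and Myog, a myogenic transcription factor, 3.11-fold (log2 change 1.64, SE 0.27, adjusted p = 0.00122). Among acetylcholine receptor subunits, Chrna1 rose 1.99-fold (log2 change 0.995, SE 0.24, adjusted p = 0.0125) and the embryonic subunit Chrng 1.71-fold (log2 change 0.77, SE 0.23, adjusted p = 0.0319). The Chrng call was lost without any 1 of the 4 arrays of 3 months or of 29 months replicates 2 and 3, with adjusted p up to 0.0945. Chrnd (log2 change 0.93, SE 0.43, adjusted p = 0.166) and the adult subunit Chrne (log2 change -0.50, SE 0.28, adjusted p = 0.26) did not pass. Of 16 members 9 rose and 1, Hdac9, fell, and adjusted over the list alone the counts were the same (median log2 change 0.85, adjusted p = 3.63e-05). The denervation response list had adjusted p = 0.583 with an estimated correlation. Within slides the list had median changes of 0.20 and 0.15, neither called, and across the slides 0.39 at 24 against 15 months.

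Of the embryonic and neonatal muscle genes, Mymx, which drives fusion of myoblasts, was at least 12.1-fold higher (adjusted p = 0.00104). No array of 3 months had it well above background. Myf6 was 2.53-fold higher (log2 change 1.34, SE 0.18, adjusted p = 0.000252) and Ankrd1 also rose, while Actc1 and Myod1 fell. Of 12 members 3 thus rose and 2 fell, 5 and 2 adjusted over the list alone, and the list was not called (median log2 change 0.20, adjusted p = 0.0978). The embryonic and neonatal muscle list had adjusted p = 0.787 with an estimated correlation. The embryonic and neonatal myosins Myh3 (log2 change 1.56, SE 0.57, adjusted p = 0.0829) and Myh8 (log2 change 0.15, SE 0.15, adjusted p = 0.545) did not pass. The adult myosins Myh4, Myh1, Myh2 and Myh7 did not pass either, with log2 changes of 0.14, -0.05, -0.08 and 1.05. The Myh8 probe was brighter at 3 months (mean log2 signal 18.95) than that of Myh4 (18.52), so it may not read neonatal myosin alone. Sln, a small inhibitor of the calcium pump, rose 10.4-fold (log2 change 3.38, SE 0.81, adjusted p = 0.012). Casq1, the calcium store protein of fast fibres, was the only 1 of 14 fast fibre genes to pass (log2 change -1.20, SE 0.16, adjusted p = 0.000217), over all genes or the list alone, and that list was not called (median log2 change -0.01, adjusted p = 0.687). The fast fibre list had adjusted p = 0.93 with an estimated correlation. Of 12 slow fibre genes limma called 0, over all genes or the list alone, and 6 had an unadjusted p under 0.05. Limma's camera called the list higher (median log2 change 0.89, adjusted p = 0.00781), a call lost without 3 months replicate 3 (adjusted p = 0.0859). The slow fibre list had adjusted p = 0.787 with an estimated correlation.

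Cdkn1a (p21), an inhibitor of the cell cycle, rose 4.42-fold (log2 change 2.14, SE 0.31, adjusted p = 0.000468), from a mean log2 signal of 9.56 ± 0.52 to 11.71 ± 0.50 (SD, n = 4). Eda2r, a p53 target and receptor of ectodysplasin A2, was at least 5.58-fold higher (adjusted p = 8.13e-06), with no probe well above background at 3 months. Cdkn2a was not tested because it was not well above background on all 4 arrays of any age. Of 20 genes of p53 and cell cycle arrest, 6 rose and 1, Cdkn1b, fell, 7 and 4 adjusted over the list alone, and the list was not called (median log2 change 0.11, adjusted p = 0.156). The p53 and cell cycle arrest list had adjusted p = 0.77 with an estimated correlation. Of the 24 antioxidant and stress genes, Srxn1 (log2 change 1.91, SE 0.25, adjusted p = 0.000219), Gclc (log2 change 0.78, SE 0.15, adjusted p = 0.00354), Hmox1 and Txnrd1 rose and Ddit3 fell, with the same counts adjusted over the list alone (median log2 change 0.24, adjusted p = 0.00456). The antioxidant and stress list had adjusted p = 0.708 with an estimated correlation. Immediate early genes had 5 of 11 higher, among them Jun (log2 change 1.33, SE 0.16, adjusted p = 0.000149) and Ccn1 (log2 change 2.21, SE 0.30, adjusted p = 0.00031), and 1, Nr4a1, lower, 7 and 2 adjusted over the list alone (median log2 change 1.20, adjusted p = 0.00265). The immediate early genes list had adjusted p = 0.601 with an estimated correlation.

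**Figure D3:**
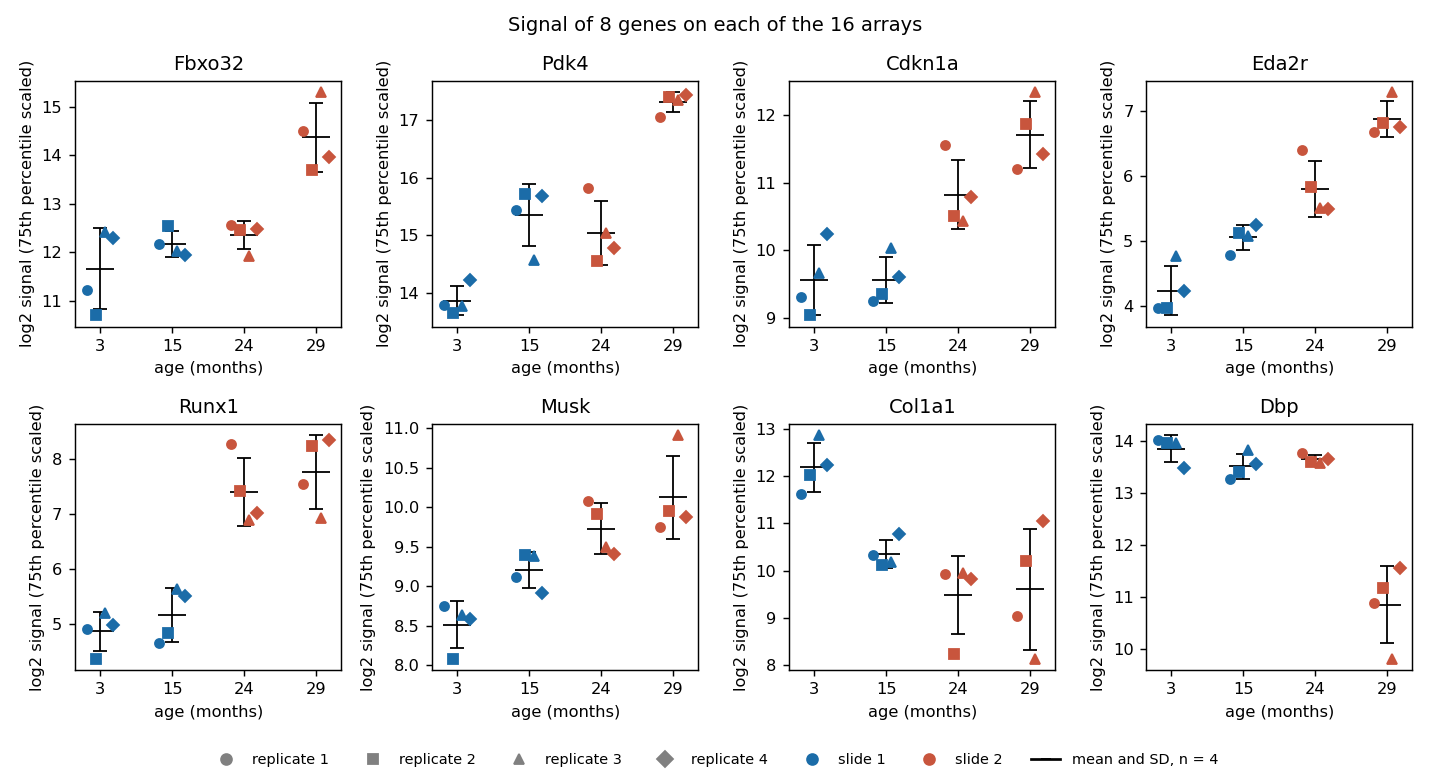
Log2 signal, scaled by the 75th percentile (vertical axes), of 8 genes at each age in months (horizontal axes), 1 point per array shaped by replicate and coloured by slide, with the mean and SD of the 4 arrays. Fbxo32 averaged 12.36 ± 0.29 at 24 months and 14.37 ± 0.71 at 29 months, Runx1 5.16 ± 0.49 at 15 months and 7.40 ± 0.62 at 24 months, and Dbp 13.65 ± 0.09 at 24 months and 10.86 ± 0.75 at 29 months.

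Several collagens and other matrix genes were lower at 29 than at 3 months. Col1a1 and Col3a1, the main fibrillar collagens, were 6.03-fold (log2 change -2.59, SE 0.53, adjusted p = 0.00477) and 4.63-fold lower (log2 change -2.21, SE 0.63, adjusted p = 0.0296), and Sparc, a collagen-binding protein, 2.06-fold lower (log2 change -1.05, SE 0.21, adjusted p = 0.00464). The Col3a1 call was lost without any 1 of 3 months replicates 2, 3 and 4 or 29 months replicates 1 and 3, with adjusted p up to 0.0802. Of 28 members 11 fell and 0 rose, 13 and 0 adjusted over the list alone (median log2 change -0.90, adjusted p = 2.73e-06). Scores at 29 months were -0.69, -0.04, -1.37 and 0.55 (replicates 1 to 4), against 0.45 to 0.91 at 3 months. The list had adjusted p = 0.77 with an estimated correlation. Within slides its median change was -0.47 at 15 against 3 months and 0.07 at 29 against 24 months. The latter turned to -0.358 (adjusted p = 0.00795) without 24 months replicate 2 and to -0.296 (adjusted p = 0.0215) without 29 months replicate 4. Cd34 fell among 16 fibroblast markers, over all genes and the list alone, in a list that was not called (median log2 change -0.54, adjusted p = 0.0669). The fibroblast markers list had adjusted p = 0.805 with an estimated correlation. The Cd34 call was lost without any 1 of the same 5 arrays (adjusted p up to 0.0785). Tendon markers had 3 of 8 lower, over all genes and the list alone, namely Fmod (log2 change -1.17, SE 0.17, adjusted p = 0.000535), Chad and Kera, a keratan sulphate proteoglycan that was at least 3.23-fold lower (adjusted p = 6.73e-05). The tendon list's call (median log2 change -0.70, adjusted p = 0.03) was lost without any 1 of 4 arrays, 3 months replicates 2 and 3 and 29 months replicates 1 and 3, with adjusted p up to 0.0639. The tendon markers list had adjusted p = 0.708 with an estimated correlation.

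Several markers of vessel cells were also lower at 29 months. Pdgfrb, a receptor of pericytes, fell 1.94-fold (log2 change -0.96, SE 0.19, adjusted p = 0.00399) and Smtn, a smooth muscle protein, 2.66-fold (log2 change -1.41, SE 0.17, adjusted p = 0.000113). Of 12 smooth muscle and pericyte markers 6 fell and 1, Mustn1, rose, with the same counts over the list alone (median log2 change -0.89, adjusted p = 0.00527), and within slides the median changes were -0.26 and -0.01. The smooth muscle and pericyte markers list had adjusted p = 0.77 with an estimated correlation. Of 17 endothelial markers Cdh5, Tek and Tie1 fell, over all genes and the list alone (median log2 change -0.39, adjusted p = 0.0289), a list call lost without any 1 of 3 months replicates 3 and 4 or 29 months replicates 1 and 3, with adjusted p up to 0.169. The endothelial markers list had adjusted p = 0.805 with an estimated correlation. The Cdh5 call was lost without any 1 of 3 months replicates 3 and 4 or 29 months replicates 2 and 3 (adjusted p up to 0.078) and that of Tek without 29 months replicate 3 (adjusted p = 0.0538).

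A few single immune genes were higher at 29 than at 3 months, with at most 1 gene called in each of the immune lists below. The chemokines Cxcl10 and Cxcl13, which attract T cells and B cells, were 32.8-fold (log2 change 5.04, SE 0.63, adjusted p = 0.00017) and at least 6.81-fold higher (adjusted p = 0.00138), with Cxcl13 well above background on 0 and Cxcl10 on 1 of the 4 arrays of 3 months. Complement C4b rose 4.23-fold (log2 change 2.08, SE 0.33, adjusted p = 0.000994) as the only 1 of 14 complement genes to pass, over all genes or the list alone. The call of the complement list (median log2 change 0.39, adjusted p = 0.0488) was lost without any 1 of 3 months replicates 1 and 4, 15 months replicate 1, 24 months replicate 1 or 29 months replicates 1, 2 and 4, with adjusted p up to 0.197. The complement list had adjusted p = 0.805 with an estimated correlation. S100a8, a calcium-binding protein of neutrophils that was above background on 2 of the arrays of 3 months, rose 13.5-fold (log2 change 3.76, SE 0.89, adjusted p = 0.011). Of 14 macrophage markers limma called 0, over all genes or the list alone, with 4 at an unadjusted p under 0.05, and the list's call (median log2 change 0.60, adjusted p = 0.0133) was lost without 29 months replicate 1 or 4, with adjusted p up to 0.104. The macrophage markers list had adjusted p = 0.776 with an estimated correlation. Among T and NK cell markers limma called 0 of 11, with 1 at an unadjusted p under 0.05 (median log2 change 0.94, adjusted p = 0.0792). The T and NK cell markers list had adjusted p = 0.787 with an estimated correlation. Among 26 interferon genes only Cxcl10 was called (median log2 change 0.22, adjusted p = 0.153), and both counts were the same over the lists alone. The interferon response list had adjusted p = 0.828 with an estimated correlation. At 29 months, replicate 1 had the highest score for the macrophage, T and NK cell and interferon lists, and replicate 4 (0.72) for complement.

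Genes of the circadian clock were shifted at 29 months. Dbp, a transcription factor of the clock output, fell 7.98-fold (log2 change -3.00, SE 0.27, adjusted p = 1.68e-05) and Hlf 2.79-fold (log2 change -1.48, SE 0.19, adjusted p = 0.000226). Each of them was lower on all 4 arrays of 29 months than on all 4 of 3 months. Of 16 clock genes 9 fell and 3 rose, among them Arntl (BMAL1), the activator of the clock, with the same counts over the list alone (median log2 change -0.63, adjusted p = 0.00892). The circadian clock list had adjusted p = 0.325 with an estimated correlation. Within slides the median change of the list was -0.02 at 15 against 3 months and -0.46 at 29 against 24 months.

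Single genes with large changes between 3 and 29 months lay partly outside these lists. Krt18, a keratin of simple epithelia that was above background on 2 of the 4 arrays of 3 months, was 78.0-fold higher (log2 change 6.29, SE 0.61, adjusted p = 2.29e-05) and Depp1, a FOXO target, 24.7-fold higher (log2 change 4.63, SE 0.59, adjusted p = 0.000199). Foxo6 fell 9.42-fold (log2 change -3.24, SE 0.39, adjusted p = 0.000133) and Nrep 9.74-fold (log2 change -3.28, SE 0.27, adjusted p = 8.13e-06). Krt18 had changed by 2.90 (SE 0.61, adjusted p = 0.0339) within slide 1, a call lost without any 1 of 3 months replicates 1, 2 and 4 or 15 months replicates 3 and 4 (adjusted p up to 0.122), and by 4.02 (SE 0.61, adjusted p = 0.0134) between 15 and 24 months. Of the muscle growth regulators, Mstn (myostatin, log2 change -0.57, adjusted p = 0.116) and Igf1 (-0.49, adjusted p = 0.0988) did not pass.

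At 24 months, compared with 3 months, Col1a1, Pdgfrb and Chodl were lower and Runx1 and Gadd45a higher, and most of the changed genes were also called at 29 months. In this comparison limma called 1014 genes, 472 higher and 542 lower, of which 734 changed at least 1.5-fold. Of these, 763 (75.2%) were called in the same direction at 29 against 3 months and 0 in the opposite one. As both comparisons use the same 3 month arrays, unchanged groups simulated against these arrays shared 3.88 genes on average over 100 draws and at most 134. Independent lists of these sizes would share 74.5, and with the 4 arrays of 3 months split 2 and 2 the shared count was 135 to 244. The arrays of 24 and 29 months both lay on slide 2 and those of 3 months on slide 1. A slide difference could thus also raise the shared count, and none of these values allows for it. The count of 1014 fell to 556, 484 or 453 without 3 months replicate 2, 3 or 4, to 585 or 496 without 24 months replicate 1 or 2, and to 558 with the 2 ages fitted alone. Without these arrays, in the same order, the shared count was 447, 400, 379, 473 and 445, and with the ages fitted alone 388.

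Runx1 was 5.78-fold (log2 change 2.53, SE 0.35, adjusted p = 0.00175), Gadd45a 2.99-fold (log2 change 1.58, SE 0.24, adjusted p = 0.00233) and Musk 2.32-fold higher at 24 than at 3 months (log2 change 1.21, SE 0.24, adjusted p = 0.0113). With Hdac4 they made 4 of 16 denervation genes higher and 0 lower, 11 and 1 adjusted over the list alone (median log2 change 0.69, adjusted p = 3.83e-06). The denervation response list had adjusted p = 0.441 with an estimated correlation. Mymx was at least 14.0-fold higher (adjusted p = 0.00295), the only 1 of 12 embryonic and neonatal muscle genes called over all genes, 4 higher and 1 lower over the list alone. That list's call (median log2 change 0.26, adjusted p = 0.0488) was lost without any 1 of 3 months replicates 2, 3 and 4, 24 months replicates 1 and 3 or 29 months replicates 1, 3 and 4, with adjusted p up to 0.131. The embryonic and neonatal muscle list had adjusted p = 0.77 with an estimated correlation. Of the slow fibre genes limma called 0 of 12, over all genes or the list alone, with 2 at an unadjusted p under 0.05. The slow fibre list's call (median log2 change 0.63, adjusted p = 0.045) was lost without any 1 of 3 months replicates 2 and 3, 24 months replicates 2 and 4 or 29 months replicate 4, with adjusted p up to 0.378. The slow fibre list had adjusted p = 0.805 with an estimated correlation. In the p53 list Cdkn1a (log2 change 1.26, SE 0.31, adjusted p = 0.0334) and Eda2r (at least 2.65-fold, adjusted p = 0.00179) rose and Cdkn1b (log2 change -1.18, SE 0.12, adjusted p = 0.000145) and Ddit4l fell, 2 and 3 adjusted over the list alone. The Cdkn1a call was lost without any 1 of 3 months replicates 1, 2 and 3 or 24 months replicates 1, 2 and 4, with adjusted p up to 0.0969. The atrophy list had Foxo1 (log2 change 1.46, SE 0.27, adjusted p = 0.00871) and Mt2 (log2 change 2.34, SE 0.38, adjusted p = 0.00341) higher of 19, 6 higher adjusted over the list alone (median log2 change 0.16, adjusted p = 0.0159), a call lost without 24 months replicate 1 (adjusted p = 0.0763). The atrophy programme list had adjusted p = 0.77 with an estimated correlation. Fbxo32 (0.70, adjusted p = 0.301) and Trim63 (0.57, adjusted p = 0.308) did not pass.

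Col1a1 fell 6.56-fold (log2 change -2.71, SE 0.53, adjusted p = 0.0105) and Sparc 2.16-fold (log2 change -1.11, SE 0.21, adjusted p = 0.00957). In all, 7 of 28 collagen and matrix genes fell and 0 rose, 13 and 0 adjusted over the list alone (median log2 change -1.02, adjusted p = 4.2e-08). The collagen and extracellular matrix list had adjusted p = 0.768 with an estimated correlation. This decrease went with low scores of 24 months replicate 2 for matrix genes (-1.34) and fibroblast markers (-1.56). Among fibroblast markers limma called 0 of 16 over all genes or the list alone, with 6 at an unadjusted p under 0.05, and the list's call (median log2 change -0.71, adjusted p = 0.00199) was lost without that array (adjusted p = 0.109). The fibroblast markers list had adjusted p = 0.77 with an estimated correlation. Pdgfrb (log2 change -1.15, SE 0.19, adjusted p = 0.00384), Cspg4, Notch3 and Kcnj8 fell among 12 smooth muscle and pericyte markers, 7 adjusted over the list alone (median log2 change -0.56, adjusted p = 0.00119). The smooth muscle and pericyte markers list had adjusted p = 0.708 with an estimated correlation. The Kcnj8 call was lost without 3 months replicate 4 (adjusted p = 0.0556). Of 17 endothelial markers 1, Cdh5, fell, 8 adjusted over the list alone (median log2 change -0.69, adjusted p = 6.23e-05). The endothelial markers list had adjusted p = 0.77 with an estimated correlation. The endothelial score was -1.14 on 24 months replicate 2 and -0.18 to 0.09 on the others of that age, and the list was called without any single array (median -0.81 to -0.34). The Cdh5 call was lost without any 1 of 11 arrays, all 8 of slide 1, 24 months replicates 1 and 2 and 29 months replicate 2 (adjusted p up to 0.128). Among satellite cell markers Chodl (log2 change -1.69, SE 0.28, adjusted p = 0.00384), above background on 1 of the 4 arrays of 24 months, and Calcr (at least 1.93-fold lower, adjusted p = 0.0146) fell of 10, 5 adjusted over the list alone (median log2 change -0.55, adjusted p = 0.00931). The satellite cell markers list had adjusted p = 0.601 with an estimated correlation. Tendon markers Fmod (log2 change -0.98, SE 0.17, adjusted p = 0.00578) and Kera (at least 3.64-fold lower, adjusted p = 0.000329) fell of 8, 4 lower and 1 higher adjusted over the list alone (median log2 change -0.76, adjusted p = 0.011). The tendon markers list had adjusted p = 0.601 with an estimated correlation. Adipocyte markers were higher as a list (median log2 change 1.17, adjusted p = 6.23e-05) with Plin4 the only 1 of 14 called, over all genes or the list alone, and with the score of 24 months replicate 4 at 2.42 against 0.15 to 0.21. The adipocyte markers list had adjusted p = 0.72 with an estimated correlation. Krt18 was 121-fold (log2 change 6.92, SE 0.61, adjusted p = 4.4e-05) and Cxcl10 31.5-fold higher (log2 change 4.98, SE 0.63, adjusted p = 0.000941), above background on 2 and 1 of the 4 arrays of 3 months, and Ces2b, a carboxylesterase, at least 12.4-fold higher (adjusted p = 0.00307). Without the 4 arrays of lowest weight the calls of Fmod and Calcr were lost, and with normexp background correction those of Calcr and of the satellite cell and tendon lists, which were also lost when probes had to be above background on all arrays.

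Between 3 and 15 months, within slide 1, the muscle had more Ostn, which encodes the muscle peptide musclin, and less Kera and Actc1. Ostn was 10.2-fold higher (log2 change 3.35, SE 0.39, adjusted p = 0.000809), with mean log2 signals of 9.90 ± 0.11 and 13.24 ± 0.66 (SD, n = 4). Mss51, a mitochondrial protein of skeletal muscle, rose 4.58-fold (log2 change 2.20, SE 0.28, adjusted p = 0.00163), Tfcp2l1 4.69-fold (log2 change 2.23, SE 0.33, adjusted p = 0.0043). Fam83g rose 4.99-fold (log2 change 2.32, SE 0.20, adjusted p = 3.94e-05) and Amy1, an amylase, 4.25-fold (log2 change 2.09, SE 0.16, adjusted p = 3.72e-05). Kera was at least 3.24-fold lower (adjusted p = 0.0036), and Actc1, the cardiac actin of developing muscle, 5.86-fold lower (log2 change -2.55, SE 0.46, adjusted p = 0.0155). Pcdhb6, a clustered protocadherin above background on 2 of the 4 arrays of 15 months, was 2.83-fold lower (log2 change -1.501, SE 0.22, adjusted p = 0.00457), Mirg, a noncoding RNA of an imprinted region, 2.76-fold lower (log2 change -1.47, SE 0.21, adjusted p = 0.00392) and Kcnu1 2.89-fold lower (log2 change -1.53, SE 0.13, adjusted p = 3.72e-05). Without 15 months replicate 2 or 4 the Actc1 call was lost, with adjusted p up to 0.0612, and without 3 months replicate 2 or 3 or 15 months replicate 2 or 4 that of Pdk4, with adjusted p up to 0.068. In the fatty acid oxidation list Pdk4 (log2 change 1.48, SE 0.27, adjusted p = 0.0167) and Ucp3 (log2 change 1.57, SE 0.24, adjusted p = 0.00597) rose, 2 of 24 over all genes and over the list alone. The list was not called (median log2 change 0.00, adjusted p = 0.276). The fatty acid oxidation list had adjusted p = 0.878 with an estimated correlation.

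limma called 213 genes at 15 against 3 months, 151 higher and 62 lower, 190 of them at least 1.5-fold. The count was 86 to 140 without any 1 of the 8 arrays of these ages, 721 with these arrays fitted alone, 802 without the 4 arrays of lowest weight, none of which belongs to these ages, and 1113 with array weights. Matrix genes were lower as a list at 15 months (median log2 change -0.47, adjusted p = 6.32e-05) with 0 of 28 called by limma over all genes, 3 lower adjusted over the list alone and 8 at an unadjusted p under 0.05. The collagen and extracellular matrix list had adjusted p = 0.77 with an estimated correlation. Complement genes were higher (median log2 change 0.47, adjusted p = 0.00375) with 0 of 14 called over all genes or the list alone and 3 at an unadjusted p under 0.05. The complement list had adjusted p = 0.77 with an estimated correlation. Cdkn1b was the only 1 of 20 genes of p53 and cell cycle arrest called (log2 change -0.87, SE 0.12, adjusted p = 0.0036), 1 higher and 4 lower over the list alone. As a list they were lower (median log2 change -0.07, adjusted p = 0.0195) unless 3 months replicate 3 was left out (adjusted p = 0.061). The p53 and cell cycle arrest list had adjusted p = 0.583 with an estimated correlation. The atrophy, adipocyte and smooth muscle lists were also called, with median changes of 0.10, 0.71 and -0.26. Their calls gave adjusted p = 0.0353, adjusted p = 0.0123 and adjusted p = 0.0271, with p-values of 0.77, 0.776 and 0.77 with an estimated correlation. In order, these calls were lost without any 1 of 3 months replicates 1 and 2 or 15 months replicate 3 (adjusted p up to 0.115), without 15 months replicate 4 (adjusted p = 0.0542) and without any 1 of 3 months replicates 3 and 4 or 15 months replicate 1 (adjusted p up to 0.123). Over all genes Foxo1 was the only 1 called of the 19 atrophy genes (log2 change 1.47, SE 0.27, adjusted p = 0.0183), a call lost without any 1 of 3 months replicates 1 and 2 or 15 months replicates 2 and 3 (adjusted p up to 0.0716). Plin4 was the only 1 of 14 adipocyte markers called (log2 change 0.90, SE 0.17, adjusted p = 0.0215), and this call was lost without any 1 of the 8 arrays of these ages except 3 months replicate 4 (adjusted p up to 0.076). Of 12 smooth muscle and pericyte markers limma called 0 over all genes, with 6 at an unadjusted p under 0.05. Adjusted over the lists alone, 2 atrophy genes and 1 adipocyte marker were higher, and 1 smooth muscle marker was higher and 4 lower.

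Between 15 and 24 months, which lay on different slides, few genes passed. Only 21 genes were called by limma, 15 higher and 6 lower, while 2922 had an unadjusted p under 0.05. Runx1 was 4.71-fold (log2 change 2.24, SE 0.35, adjusted p = 0.0205), Gadd45a 2.98-fold (log2 change 1.58, SE 0.24, adjusted p = 0.0131) and Krt18 16.2-fold higher at 24 months (log2 change 4.02, SE 0.61, adjusted p = 0.0134). Also higher were Gdf5, a growth factor of the bone morphogenetic protein family (5.85-fold, log2 change 2.55, SE 0.37, adjusted p = 0.0106), Sox4 (2.34-fold, log2 change 1.22, SE 0.15, adjusted p = 0.00873) and Stk33 (3.03-fold, log2 change 1.60, SE 0.19, adjusted p = 0.00873), above background on 2 of the 4 arrays of 15 months. Chodl (log2 change -1.77, SE 0.28, adjusted p = 0.0205), above background on 1 array of 24 months, Gnao1 (log2 change -0.99, SE 0.13, adjusted p = 0.00873) and Mapk10 (log2 change -1.22, SE 0.18, adjusted p = 0.0106), above background on 2, fell. Of 16 denervation genes 2 rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 change 0.39, adjusted p = 2.73e-06). The denervation response list had adjusted p = 0.441 with an estimated correlation. The interferon list was higher with 0 of 26 called by limma and 5 at an unadjusted p under 0.05 (median log2 change 0.48, adjusted p = 9.02e-05). The interferon response list had adjusted p = 0.77 with an estimated correlation. The fibroblast list was lower with 0 of 16 called and 6 at an unadjusted p under 0.05 (median log2 change -0.77, adjusted p = 0.000168), with its lowest score on 24 months replicate 2. The fibroblast markers list had adjusted p = 0.77 with an estimated correlation. The calls of Runx1, Gadd45a, Krt18, Gdf5 and Chodl were lost without 15 months replicate 1 or 2, and those of Gnao1 and Mapk10 without replicate 2. Those of Runx1, Krt18 and Chodl were also lost without 24 months replicate 1, those of Runx1 and Chodl without 24 months replicate 2, and that of Chodl without 15 months replicate 4, with adjusted p up to 0.0922. Without 15 months replicate 2 only 2 genes were called, Sox4 and Stk33, without replicate 1 of that age 10, and without 24 months replicate 3 or 4 or 29 months replicate 1 there were 44, 46 and 88.

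Between 24 and 29 months, within slide 2, Pdk4, Fbxo32, Trim63 and Gabarapl1 rose and the clock genes Dbp, Hlf and Ciart fell. Acot1 and Acot2, thioesterases of fatty acyl-CoA, were 8.89-fold (log2 change 3.15, SE 0.32, adjusted p = 0.000443) and 7.29-fold higher (log2 change 2.87, SE 0.20, adjusted p = 7.06e-06). Pdk4 was 4.78-fold higher (log2 change 2.26, SE 0.27, adjusted p = 0.00196) and Angptl4 7.01-fold higher (log2 change 2.81, SE 0.45, adjusted p = 0.00699). Pdk4, Angptl4 and Ucp3 were the 3 of 24 genes called in the fatty acid oxidation list, which does not hold Acot1 and Acot2, with 0 lower, and 6 and 0 adjusted over the list alone (median log2 change 0.31, adjusted p = 6.94e-08). The fatty acid oxidation list had adjusted p = 0.708 with an estimated correlation. Fbxo32 rose 4.04-fold (log2 change 2.01, SE 0.38, adjusted p = 0.0161), Trim63 3.36-fold (log2 change 1.75, SE 0.31, adjusted p = 0.0123) and Klf15 1.80-fold (log2 change 0.85, SE 0.16, adjusted p = 0.0149). In the atrophy list 5 of 19 atrophy genes were higher, 11 adjusted over the list alone, with 0 lower (median log2 change 0.46, adjusted p = 4.28e-09). The atrophy programme list had adjusted p = 0.325 with an estimated correlation. Gabarapl1 (log2 change 1.37, SE 0.19, adjusted p = 0.00455) and Ulk1 (log2 change 0.84, SE 0.15, adjusted p = 0.0115) rose with Ctsl, 3 of 24 autophagy and lysosome genes, 5 adjusted over the list alone (median log2 change 0.17, adjusted p = 5.5e-06). The autophagy and lysosome list had adjusted p = 0.583 with an estimated correlation. Dbp fell 6.93-fold (log2 change -2.79, SE 0.27, adjusted p = 0.000296), Hlf 2.49-fold (log2 change -1.32, SE 0.19, adjusted p = 0.00569) and Ciart, above background on 1 of the 4 arrays of 29 months, 8.87-fold (log2 change -3.15, SE 0.64, adjusted p = 0.0235). With Arntl, which rose, 6 of 16 clock genes fell and 1 rose, 9 and 3 adjusted over the list alone (median log2 change -0.46, adjusted p = 6.32e-05). The circadian clock list had adjusted p = 0.0808 with an estimated correlation. The Ciart call was lost without any 1 of 24 months replicates 2 and 4 or 29 months replicates 2, 3 and 4 (adjusted p up to 0.0709).

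In the p53 list Sesn1 (log2 change 1.43, SE 0.29, adjusted p = 0.0229), Btg2 and Eda2r (log2 change 1.08, SE 0.22, adjusted p = 0.0237) rose of 20, 8 adjusted over the list alone (median log2 change 0.35, adjusted p = 0.000204). The p53 and cell cycle arrest list had adjusted p = 0.29 with an estimated correlation. Cdkn1a (0.88, adjusted p = 0.176) did not pass. The Sesn1 call was lost without any 1 of 24 months replicates 2, 3 and 4 (adjusted p up to 0.0661), that of Eda2r without any 1 of these or 29 months replicate 3 (adjusted p up to 0.0771). Srxn1 (log2 change 1.37, SE 0.25, adjusted p = 0.0135) was the only 1 of 24 antioxidant and stress genes called, 7 over the list alone, in a list that rose (median log2 change 0.19, adjusted p = 0.000437). The antioxidant and stress list had adjusted p = 0.601 with an estimated correlation. Scd1, which desaturates fatty acids, and Retn (resistin), made by fat cells, fell 9.63-fold (log2 change -3.27, SE 0.67, adjusted p = 0.0237) and 6.63-fold (log2 change -2.73, SE 0.66, adjusted p = 0.0496), 2 of 14 adipocyte markers, 6 adjusted over the list alone. The list's call (median log2 change -1.501, adjusted p = 0.00362) was lost without 24 months replicate 4, whose adipocyte score was 2.42 (adjusted p = 0.116). The adipocyte markers list had adjusted p = 0.77 with an estimated correlation. The Scd1 call was lost without any 1 of 24 months replicate 2 or 29 months replicates 2 and 3 (adjusted p up to 0.0771). The Retn call was lost without any 1 of the 16 arrays except 24 months replicate 1 and 29 months replicate 4 (adjusted p up to 0.139).

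limma called 417 genes at 29 against 24 months, 320 higher and 97 lower, 283 of them at least 1.5-fold. The count fell to 158, 206 or 194 without 24 months replicate 2, 3 or 4, to 153 without 29 months replicate 3 and to 270 without 15 months replicate 2. Another split of the 8 arrays called 1766 genes, more than the ages did. It set 24 months replicates 1 and 3 with 29 months replicates 2 and 4 against the 4 arrays of lowest weight. The count for the ages was 52 without these 4 arrays, 31 of the 52 among the 417. With the 8 arrays fitted alone it was 9, against 417 when all 16 shared the spread. In the fit of all arrays 3330 genes had an unadjusted p under 0.05. Fitted alone, these ages no longer gave calls for Fbxo32, Trim63, Klf15, Gabarapl1, Ulk1, Srxn1, Hlf and Angptl4. Without the 4 arrays, all of these but Angptl4 were lost, and Pdk4 as well (adjusted p up to 0.0549 for Pdk4). The calls of Acot1, Acot2 and Dbp held under every alternative run.

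**Figure D4:**
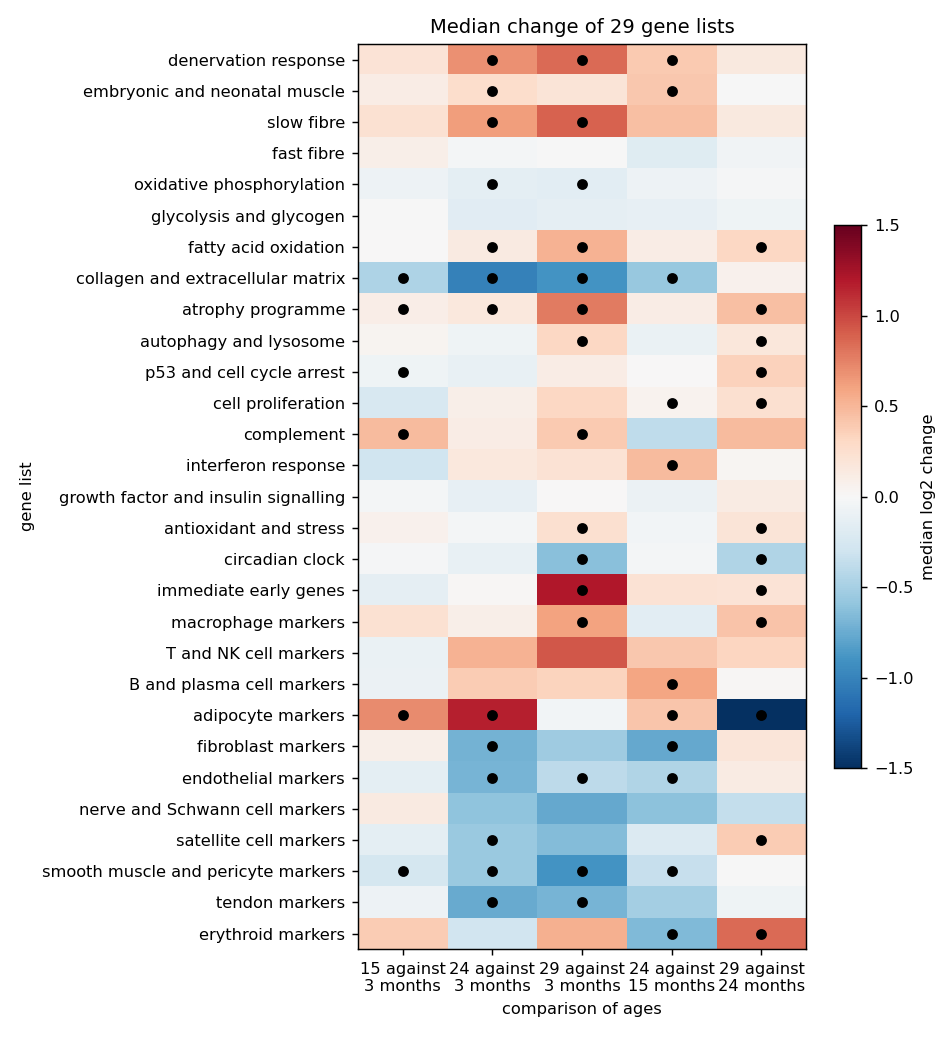
Median log2 change of 29 gene lists (vertical axis) in the 5 comparisons of ages (horizontal axis), coloured from blue (lower at the older age) to red (higher), with a dot where limma's camera called the list at its preset correlation. The matrix list was lower at 29 against 3 months (-0.90), and 0 of the 57 dots held with an estimated correlation.

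The lists gave weaker evidence than the single genes. With camera's preset correlation 57 of 145 tests were called, 6 at 15 against 3 months, 13 at 24 against 3, 15 at 29 against 3, 11 at 24 against 15 and 12 at 29 against 24 months. After adjustment none held with an estimated correlation, while 11 had an unadjusted p under 0.05 there, and fry, which asks only whether the genes of a list move one way, called 18. These 11 included the denervation list in the 3 comparisons of 24 or 29 months with 3 months and of 24 with 15 months, the atrophy and clock lists at 29 against 3 and against 24 months. The others were p53 and cell cycle arrest at 15 against 3 and at 29 against 24 months, satellite cell markers at 24 against 3 months and autophagy at 29 against 24 months.

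A straight line in age with slide as a block, which uses the differences within slides, changed 138 genes, 86 upward and 52 downward. Among the 86 upward were Ostn, by 0.22 on the log2 scale per month (SE 0.04, adjusted p = 0.0292), Pdk4 by 0.17 (adjusted p = 0.0392), Mss51 by 0.17 (adjusted p = 0.00225), Fam83g by 0.17 (adjusted p = 0.00274) and Tfcp2l1 by 0.16 (adjusted p = 0.0207). Pdk4 rose in both steps, by 1.48 and 2.26, whereas the Ostn step was 3.35 from 3 to 15 months and -0.46 from 24 to 29 months. The 2 steps were 2.32 and 0.04 for Fam83g, 2.23 and 0.01 for Tfcp2l1 and 2.20 and 0.51 for Mss51. The rates of these 3 genes thus mostly reflect the longer step from 3 to 15 months and not a steady rise. Among the 52 downward were Kera (adjusted p = 0.0168), Actc1 (-0.18 per month, adjusted p = 0.0479), Fras1 (adjusted p = 0.047), Aplnr (-0.14, adjusted p = 0.0403) and Dusp14 (-0.12, SE 0.02, adjusted p = 0.00509). Dusp14, a phosphatase, fell in both steps by 1.28 and 1.09, whereas Actc1 changed by -2.55 and 0.02 and Aplnr by -1.82 and -0.45. Of these 10 genes, the calls of Mss51, Fam83g and Dusp14 held without any single array, and those of the other 7 were lost without 3 months replicate 4, and without further single arrays each, with adjusted p up to 0.145. The count was 61, 76 or 60 without 3 months replicate 2, 3 or 4 and 60, 52 or 67 without 15 months replicate 2, 3 or 4, and 2240 with slide as a random block. Kera was above background on all 4 arrays of 3 months and on 0 at the later ages, and Fras1 on all 4 of 3 months and 0 of 29 months, so no rate is given for them. Aplnr was above background on 2 arrays of 29 months.

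The change from 24 to 29 months differed from that from 3 to 15 months in 146 genes, by a test of the difference itself, 69 with a positive difference (later step minus earlier step) and 77 with a negative one. Pfkfb3, an enzyme that drives glycolysis, went down by 1.66 from 3 to 15 months and up by 1.87 from 24 to 29 months (difference 3.53, SE 0.61, adjusted p = 0.0192). Acot1 changed by 0.39 in the first step and 3.15 in the second (difference 2.76, SE 0.46, adjusted p = 0.0148). In the other direction, Ostn had a difference of -3.81 (SE 0.55, adjusted p = 0.00736), and Neto2, above background on 1 of the 4 arrays of 3 months, which went up by 1.82 and fell by 1.29, of -3.11 (SE 0.43, adjusted p = 0.00574). The 4 calls held without any single array. The count fell to between 55 and 94 without any 1 of 10 arrays, 3 months replicates 1, 3 and 4, all 4 of 15 months, 24 months replicates 2 and 4 and 29 months replicate 4.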

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

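The slide tests of matrix genes and of the genes called at 29 against 3 months, the test of fibroblast share and that of the 2 clock limbs were chosen only after the results were seen. Each list score was tested for an array far from the other 3 of its age by Dixon's test, which marks about 1 in 20 groups by chance, and 7 of 116 were marked. The T and NK cell score was 2.84 on 29 months replicate 1 (others -0.25 to -0.05) and the adipocyte score 2.42 on 24 months replicate 4 (others 0.15 to 0.21). On 29 months the atrophy score was 1.11 on replicate 3 (others 0.44 to 0.51) and the fast fibre score -0.35 on replicate 1 (others -0.06 to 0). The slow fibre score was 0.86 on 15 months replicate 4 (others -0.58 to -0.48). On 3 months replicate 2 the denervation score was -0.55 (others -0.37 to -0.35) and the immediate early score -0.60 (others -0.09 to -0.02).

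The same test marked 34 of 480 groups of 4 log2 signals of the 120 genes named, given as the array's value against the other 3 of its age. 3 months replicate 1 stood apart for Cxcl10 at 5.14 against 2.48 to 2.61 and Ulk1 at 13.26 against 13.01 to 13.03. 3 months replicate 2 stood apart for Gdf5 at 6.03 against 6.45 to 6.53 and Ncam1 at 7.12 against 7.59 to 7.62. 3 months replicate 3 stood apart for Mbp at 5.77 against 6.51 to 6.59. 3 months replicate 4 stood apart for Chrng at 4.88 against 5.26 to 5.32, Dbp at 13.48 against 13.96 to 14.03 and Mirg at 7.40 against 7.81 to 7.89. 15 months replicate 1 stood apart for Depp1 at 8.60 against 9.64 to 9.82, S100a8 at 6.38 against 5.04 to 5.23 and Ulk1 at 13.28 against 13.23 to 13.24. 15 months replicate 4 stood apart for Chrne at 6.86 against 7.92 to 8.08, Myh7 at 17.30 against 15.72 to 15.81 and Sdc4 at 7.70 against 7.23 to 7.25. 24 months replicate 1 stood apart for Myf6 at 13.79 against 12.86 to 12.98. 24 months replicate 2 stood apart for Cdh5 at 8.55 against 9.87 to 10.14, Col1a1 at 8.23 against 9.82 to 9.95, Col3a1 at 8.01 against 10.12 to 10.55 and Tie1 at 6.44 against 7.99 to 8.02. 24 months replicate 3 stood apart for Chrne at 7.54 against 6.96 to 7.05, Fbxo32 at 11.93 against 12.47 to 12.56 and Kcnu1 at 5.50 against 5.36 to 5.38. 24 months replicate 4 stood apart for Cxcl13 at 8.16 against 4.34 to 4.59, Ppargc1a at 11.27 against 11.87 to 11.95, Retn at 12.04 against 8.69 to 8.97 and Scd1 at 12.21 against 8.65 to 9.24. 29 months replicate 1 stood apart for Bdnf at 5.31 against 6.53 to 6.56, Myh4 at 18.42 against 18.71 to 18.77 and Myh7 at 16.11 against 17.16 to 17.37. 29 months replicate 2 stood apart for Ccn1 at 11.10 against 11.67 to 11.72. 29 months replicate 3 stood apart for Ces2b at 4.73 against 7.32 to 7.56, Plin4 at 15.89 against 15.11 to 15.19 and Sesn1 at 13.59 against 11.84 to 12.03. 29 months replicate 4 stood apart for Casq1 at 13.56 against 13.17 to 13.19.

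The step from 24 to 29 months differed from that from 3 to 15 months in 146 genes, by a test of the difference itself. Positive differences included those of Pfkfb3 (3.53), Acot1 (2.76), Slc43a1 (2.75) and Btg2 (2.25), and negative ones those of Scd1 (-4.73), Ostn (-3.81), Neto2 (-3.11) and Col24a1 (-2.96). The fitted values of Kera (2.93) and Tmem45b (-5.30) are set by background and give no size, as Kera was not above background at 15, 24 and 29 months, nor Tmem45b at 3 and 29 months. The calls of Slc43a1, Btg2, Scd1, Kera, Tmem45b and Col24a1 were each lost without 3 months replicate 4 and without other single arrays, with adjusted p up to 0.105.

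Among control spots, which no comparison used, 1 of 96 spike-in control probes lay above the mean plus 3 SD of the negative control spots on all 16 arrays. No explanation was tested.

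Several fatty acid, atrophy and clock genes shifted between 24 and 29 months. The array's row on the slide is argued against, since genes called at 29 against 24 months had a slope of 0.08 (0.04 to 0.10 without single arrays) for 15 against 3 months, where the row would give a slope near -1. The limb of Arntl and that of Dbp moved apart by 2.03 (1.88 to 2.27), but these genes prompted the test, so this value decides nothing. Of 5 clock outputs outside the list 4 moved with their limb and 1 against it, with 1 called by limma and a mean signed by limb of 0.54 (0.41 to 0.62). A different time of day at dissection is a candidate explanation that stays open for the clock genes, and it cannot be told apart from a change of the clock with age. Food withdrawal or stress hormones cannot be told apart from ageing, because 7 glucocorticoid targets had a median change of 0.42 (0.27 to 0.54), between the values that would decide, with 0 called by limma, and ageing itself stays open and untested.

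Several matrix genes were lower at 29 than at 3 months. A slide difference stays open. Within slide 1 the list median was -0.47 (-0.52 to -0.38 without single arrays) at 15 months, with 0 called on the same 3 month arrays. Within slide 2 it was 0.07. A lower share of fibroblasts cannot be told apart from lower expression per cell. The matrix median minus the fibroblast marker median was -0.36 (-0.63 to -0.10), too close to the bound of the test for its spread. Several matrix genes are made by the same cells.

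The genes called at 29 against 3 months lie across slides. Over these genes the change from 15 to 24 months, on the same slides with other arrays, had a slope of 0.26 (0.25 to 0.30). A slide difference alone would give near 1. As each age lay on 1 slide, a slide cause stays open for single genes and the denervation list, called only across slides. Without 29 months replicates 1 and 3 the changes had a slope of 0.94 (0.93 to 0.95) on those with all arrays. Both share arrays, so this decides nothing. At 29 against 3 months age was not tested apart from the slide, which only comparisons within 1 slide and the line allow.

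Other splits of the same arrays were counted for each result, the real split included. For genes changed, only the real split of 35 gave as many in 4 comparisons. These were 15 against 3 months (213, highest other 0) and 24 against 3 months (1014, highest other 0). The others were 29 against 3 months (3190, highest other 0) and 24 against 15 months (21, highest other 1). This alone cannot exclude chance, since 1 of 35 is the lowest share possible and the tests were not adjusted for their number. Splits that mix the ages also carry their difference in the spread, which lowers their counts. At 29 against 24 months 2 of 35 splits gave as many, so chance cannot be excluded. The split of 24 months replicates 1 and 3 with 29 months replicates 2 and 4 against the rest called 1766 genes against 417, which points to a structure of the samples other than age. Of 100 draws of ages within slides, the real one included, 1 gave as many genes for the line (138, highest other 63). For the difference of steps 3 did (146, highest other 586). Few draws thus reached the real counts, but these tests were not adjusted for their number either. The 586 genes also point to a structure of the samples. For list calls, chance cannot be excluded in any comparison. As many were called in 25 of 35 splits at 15 against 3 months (6, highest other 12), 2 at 24 against 3 (13, highest other 13), 3 at 29 against 3 (15, highest other 16), 17 at 24 against 15 (11, highest other 17) and 18 at 29 against 24 months (12, highest other 19).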

How the results depend on the processing

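The normexp setting and the fits without the 2 or 4 arrays of lowest weight were chosen only after the results were seen. Of 196 called values of named genes, 94 kept their call under every alternative run and 0 reversed. Of 57 list calls none kept it under every alternative, since 0 held with an estimated correlation and 18 tests were called by fry, and 23 kept it under all others. Counts within 1.5 times are not given, and the cause was not tested except where fewer arrays, genes or calls explain it.

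Scaling by the median gave 89 genes at 15 against 3, 512 at 24 against 3, 1537 at 29 against 3 and 249 at 29 against 24 months, 68 for the line, 55 for the difference of steps and 361 shared. It moved the median of all genes by -0.13 at 24 against 3 and 24 against 15 months and by 0.12 at 29 against 24 months, and the share of higher calls from 71.4% to 55.6% at 24 against 15 and from 76.7% to 90.8% at 29 against 24 months. Normexp gave 1842 at 24 against 3 and 672 at 29 against 24 months and 410 for the difference, with 58.0% higher (from 70.9%) at 15 against 3 and 45.2% at 24 against 15 months. The deposited values gave 1097 at 29 against 24 months and 963 for the difference, with 59.2%, 46.4% and 60.4% higher at 15 against 3, 24 against 15 and 29 against 24 months. Without a filter 106, 470 and 153 genes were called at 15 against 3, 24 against 3 and 29 against 24 months, 66 for the line, 50 for the difference and 375 shared. The filter on all arrays gave 10 at 24 against 15 months.

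With only the ages compared in the fit the counts were 721, 558, 1983, 13 and 9 (15, 24 and 29 against 3, 24 against 15, 29 against 24 months) and 388 shared. Array weights gave 1113 at 15 against 3, 139 at 24 against 15 and 229 at 29 against 24 months, 1092 for the line and 266 for the difference. Without the 4 arrays these were 802, 9 and 52, and 585 for the line, and without the 2 arrays 332 at 15 against 3 and 273 at 29 against 24 months, 243 for the line and 90 for the difference. At least 1.5-fold left 1951 at 29 against 3 months. Slide as a random block gave 2240 for the line, since it then also uses differences between slides. Same-numbered arrays did not deviate together (r -0.471 to 0.303, over 0.1 in 6 of 24 pairs, and 2 of 16 arrays correlated best with their own number). With the replicate block the counts were 32 at 24 against 15 and 258 at 29 against 24 months and 87 for the line.

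Leaving out 1 array gave 86 to 279 genes at 15 against 3, 453 to 1282 at 24 against 3, 2185 to 3544 at 29 against 3, 2 to 88 at 24 against 15 and 153 to 562 at 29 against 24 months, 52 to 202 for the line, 55 to 165 for the difference, 379 to 837 shared and 49 to 65 list calls.

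Some medians reversed. Ncam1 was -0.97 at 24 against 3 months in the deposited values (adjusted p = 0.0379). Without the 4 arrays oxidative phosphorylation was 0.043 at 29 against 3 months and adipocyte markers, whose test changed sign, -0.16 at 29 against 24 months. Without the 2 arrays proliferation was -0.009, interferon -0.41 and macrophage markers -0.16 at 29 against 24 months. Leaving out single arrays moved matrix genes from -0.36 (24 months replicate 2) or -0.30 (29 months replicate 4) to 0.34, oxidative phosphorylation from -0.14 to 0.11 (29 months replicate 1) and interferon from -0.47 (29 months replicate 1) to 0.35 at 29 against 24 months, and adipocyte markers from -0.23 (24 months replicate 4) to 0.70 at 24 against 15 months. Signal over background, with 48.0% to 60.9% of spots above it, limits dim genes.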

Other observations

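The lists of imprinted genes and beta protocadherins were chosen only after Mirg and Pcdhb6 were seen among the lowest genes at 15 against 3 months. Several clustered beta protocadherins, adhesion proteins encoded side by side, were lower at 15 than at 3 months. Of 21 listed genes, without Pcdhb6, 7 were measured, all 7 were below 0 and 4 were called lower at 15 against 3 months (median -1.14, -1.23 to -1.04 without single arrays, camera p = 1.03e-11, and p = 7.93e-05 with an estimated correlation). At 29 against 3 months 6 were called lower (median -1.07), and at 29 against 24 months limma called 0 (median -0.24). Pcdhb12 did not pass at 15 against 3 months in the limma fit (log2 change -0.07, adjusted p = 0.961). A fall of several members of the cluster after 3 months may account for Pcdhb6, although related members can share signal on their probes. Imprinted growth genes had a median of -0.14 (-0.28 to -0.09) with 13 of 18 below 0 and 0 called by limma at 15 against 3 months (camera p = 0.006, and p = 0.0265 with an estimated correlation). At 29 against 3 months 5 were called lower and 1 higher. The median at 15 months lay on both sides of the bound of -0.2 when single arrays were left out, which leaves a joint fall with Mirg open.

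Cell proliferation genes had Mki67 and Mcm6 higher of 16 at 29 against 3 months (median log2 change 0.31, adjusted p = 0.0849), with the same count adjusted over the list alone. The cell proliferation list had adjusted p = 0.803 with an estimated correlation. Growth factor and insulin signalling genes had 4 of 22 higher, among them Insr and Bdnf, and 4 lower, among them Igfbp5 (log2 change -1.59, SE 0.30, adjusted p = 0.00308) and Irs1 (log2 change -1.04, SE 0.19, adjusted p = 0.00256), 5 and 7 adjusted over the list alone, and the list's median (0.01) and test differed in sign (adjusted p = 0.842). Nerve and Schwann cell markers had a median of -0.76, adjusted p = 0.0554. The nerve and Schwann cell markers list had adjusted p = 0.805 with an estimated correlation. Over all genes 1 of 16 was higher, Mbp, and 1 lower, against 1 and 3 adjusted over the list alone, and 10 had an unadjusted p under 0.05. Another Mbp probe went the opposite way. B and plasma cell markers had 1 of 7 higher, Jchain (median log2 change 0.34, adjusted p = 0.12). The B and plasma cell markers list had adjusted p = 0.787 with an estimated correlation. Erythroid markers were higher at 29 against 24 months (median log2 change 0.85, adjusted p = 0.000651) and lower at 24 against 15 months (median log2 change -0.67, adjusted p = 0.013), where limma called 0 of 8 and 4 and 2 had an unadjusted p under 0.05. The erythroid markers and erythroid markers lists had adjusted p = 0.708 and 0.77 with an estimated correlation. At 24 months replicate 2 scored -1.30 against -0.39 to 0.37. The call at 24 against 15 months was lost without this array or 15 months replicate 1 (adjusted p up to 0.113). That at 29 against 24 months remained without any single array (adjusted p up to 0.00807) and was lost without the 4 arrays of lowest weight. Satellite cell markers were higher at 29 against 24 months with Sdc4 called (median log2 change 0.38, adjusted p = 0.0252). The satellite cell markers list had adjusted p = 0.708 with an estimated correlation. This call was lost without 24 months replicate 2 or 29 months replicate 2 (adjusted p up to 0.145).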
